A study of Homo sapiens with 20 samples.

How the data were processed

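RNA sequencing measured transcript levels in alveolar macrophages, the resident phagocytes of the airspaces, recovered by bronchoalveolar lavage in sarcoidosis, a granulomatous disease. Per the labels' protocols, the isolated cells were cultured for 16 h with or without dexamethasone, a synthetic glucocorticoid, at 100 ng/mL. Messenger RNA was isolated with oligo(dT) beads and turned into strand-specific libraries, which were pooled and sequenced as paired ends over 75 cycles. The groups were taken from the treatment label, and the replicate names from the sample titles. The labels put 10 libraries in each group.

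The authors deposited 1 table of raw whole-number read counts per gene symbol, with 1 column per library. Per the submitters' processing notes, STAR, DESeq2 and the hg19 genome build were used, with no version or role. The counting program, its strand setting and the gene annotation were not given in the sources used here. Reads shared between near-identical genes could therefore have been split or lost, which makes single values of the HLA genes, the metallothioneins, HSPA1A and HSPA1B, and the alpha-globins uncertain. Overlapping genes on opposite strands carry the same reservation.

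The table held 23710 entries. In 28 of them a spreadsheet had turned the gene symbol into a date. These entries held 0.191 to 0.259% of the counts of a library. They were left out of tests and CPM values, which left 23682 named genes, but the total counts given per library include them. Older symbols were matched to list members through the synonyms of the RefSeq annotation, so that IL8, CTSL1, ATP5B and C19orf59 are given as deposited. No coordinates were used. Transcript GC content and length came from GENCODE 29, a newer annotation than the build of the counts, matched by symbol for 10648 of the 10853 tested genes (98.1%).

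Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr at a minimum count of 10, libraries were scaled by the trimmed mean of M values (TMM), and the groups were compared with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all tested genes at 0.05. The model held the group only. Log2 fold changes are given with their standard error (SE) and CPM values, scaled by TMM, with the standard deviation (SD) between libraries. The 23 pathway lists, the 9 lists of other cell types and the 3 lists of RNA quality were fixed before the data were examined. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on voom values at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry. Adjusted p-values of lists were computed over the 23 pathway lists and separately over the 4 testable lists of other cells and RNA quality.

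The genes named in the text followed a rule set before the data were examined. It took the 8 genes that rose and the 8 that fell with the smallest adjusted p among those with a mean of at least 5 CPM and an absolute log2 fold change of at least 1. It added up to 4 members of each pathway list and up to 2 of each other list, by adjusted p, and 10 genes named in advance (NR3C1, FKBP5, TSC22D3, DUSP1, CD163, TNF, IL1B, IL6, IL8 and CCL18). The rule left out small RNA genes, genes known only by a provisional locus symbol, XIST and Y-linked genes. It named 125 genes. Other members of the fixed lists, and other genes where stated, were picked for mention after their values were seen.

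Alternatives covered DESeq2 1.42.0, limma-voom with and without quality weights, other scalings, other filters, surrogate variables (sva 3.50.0), the replicate number as a block, a fold change minimum and other list tests. Alternatives added after the data had been seen were a correction of each library for a spline on GC content with 5 degrees of freedom, leaving out libraries, and a permutation test of the list means. That last test permuted the group labels of the 20 libraries 100000 times on the mean log2 CPM of a list's tested members. It keeps the correlation between genes and does not compare a list with other genes. Differences between the groups in 17 library measures used two-sided permutation tests with 100000 resamples.

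Total counts per library ran from 99634 to 26787403. Zero counts are given with the level that 3 counts would have had. Such limits cover counting error only, since reads amplified without molecular identifiers are not independent molecules. Each of the 90 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 6.94, so all 20 libraries were counted separately. The lowest value among untreated pairs was 7.09, for replicates 2 and 9. Such values speak against 1 library deposited more than once and cannot tell whether libraries shared a donor. Every deposited column belonged to a library of this series.

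The tests were first tried on simulated counts for the 10853 genes in 10 against 10 libraries. There, 75 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were recovered, and 3 unchanged genes were called. With an added difference between the groups of 0.3 log2 units per SD of GC content, 495 unchanged genes were called without the GC correction and 8 with it. The simulated counts were independent between genes and between libraries, and every library of a group had the same GC trend. No simulated library departed from its group, so these rates may not hold for the real libraries. In a simulation that shifted the glucocorticoid receptor targets 2-fold, that list was called, and 1 of the other lists was called as well. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.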

Results

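The data compare the transcripts of alveolar macrophages from sarcoidosis lavage samples between 10 untreated and 10 dexamethasone libraries after 16 h of culture. Untreated libraries held 2817923 to 26787403 counts (median 3895231) and had counts in 14195 to 18278 genes. Dexamethasone libraries held 99634 to 21057352 (median 2262722.5), with counts in 9203 to 16156 genes. The smallest was dexamethasone replicate 9. The labels do not say whether the 20 libraries came from separate donors, so p-values measure the spread between these libraries. The labels also give no batch, and a batch that followed the groups could not be told apart from dexamethasone. The question, as the series title puts it, is which transcriptional signature dexamethasone leaves in these cells.

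From untreated to dexamethasone libraries, 14 of 18 tested targets of the glucocorticoid receptor rose and 1 fell, while the co-receptor endoglin, a gelatinase, and many lysosomal, mitochondrial and antigen-presenting genes fell. FKBP5, a chaperone partner that restrains the receptor, went from 249 ± 75.2 to 1606 ± 509 CPM (SD, n = 10 libraries per group), and TSC22D3, which encodes the anti-inflammatory protein GILZ, from 39.1 ± 9.0 to 515 ± 252 CPM. ENG, the TGF-beta co-receptor endoglin, fell from 299 ± 62.7 to 79.8 ± 19.8 CPM, and LGALS9, the lectin galectin-9, from 245 ± 45.8 to 58.6 ± 17.5 CPM. MMP9, a secreted gelatinase, fell 16.7-fold on average, from 749 ± 559 to 47.1 ± 55.4 CPM. The receptor gene itself, NR3C1, stood at 342 ± 45.7 and 330 ± 87.3 CPM, a log2 fold change of -0.04 ± 0.14 (SE; edgeR quasi-likelihood adjusted p = 0.827). Its level was highest, at 505 CPM, in the library labelled dexamethasone replicate 7. With a GC correction of each library and without dexamethasone replicates 7 and 9, NR3C1 passed as a fall.

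Of 10853 genes tested, 4644 (42.8%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 2243 were higher and 2401 lower with dexamethasone, and 1200 differed at least 2-fold, 517 higher and 683 lower. The biological coefficient of variation was 0.368. Higher genes with the smallest adjusted p were NAA38 (log2 fold change 1.22 ± 0.11), FKBP5 (2.69 ± 0.25), FMN1 (2.92 ± 0.27), FOXN2 (1.42 ± 0.14), TSC22D3 (3.73 ± 0.37), IRAK3 (1.85 ± 0.19), SESN1 (2.30 ± 0.24) and FOXO3 (1.70 ± 0.18). The symbol NAA38 has been used for more than 1 gene and is given as deposited. FOXO3 is a transcription factor restrained by insulin signalling, and SESN1, a sestrin, belongs to the stress-response proteins that restrain mTORC1. Lower genes were ENG (-1.89 ± 0.15), LGALS9 (-2.06 ± 0.17), POLD1 (-2.21 ± 0.20), GMIP (-1.43 ± 0.13), PRAM1 (-2.74 ± 0.25), DENND4B (-1.10 ± 0.11), FAM89B (-1.40 ± 0.14) and EFHD2 (-1.38 ± 0.14). Each of these 8 lay below all untreated libraries in 10 of 10 dexamethasone libraries. In replicate 9 this rests on few reads: PRAM1 had 2 counts, and POLD1 and FAM89B had 0, which allows up to 26.3 CPM. All 8 kept their calls in 35 alternative settings, but not all kept a 2-fold change. The weakest log2 fold changes were -0.59 for DENND4B, -0.63 for FAM89B, -0.84 for EFHD2 and -0.86 for GMIP. ENG, LGALS9, POLD1 and PRAM1 stayed beyond 2-fold.

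The direction of change followed transcript GC content. Across 10648 genes, which are not independent replicates, Spearman's rho between log2 fold change and GC was -0.565, against 0.0712 with transcript length. In the tenth of genes with the least GC the median log2 fold change was 0.44, with 546 genes higher and 20 lower, and in the tenth with the most it was -0.61, with 27 higher and 606 lower. The slope of expression on GC, measured per library relative to the mean of all 20, averaged 0.211 ± 0.0748 in untreated and -0.211 ± 0.170 in dexamethasone libraries (SD, permutation p = 2e-05, adjusted p = 0.00034 over 17 library measures). Slopes of all 10 dexamethasone libraries lay below those of all untreated ones, though dexamethasone replicate 9, the smallest library, stood at 0.1205 against 0.1224 for the lowest untreated one. After a GC correction of each library, chosen after the data had been seen, 3043 genes passed edgeR's adjusted p of 0.05, 1291 higher and 1752 lower. The correction kept 2111 of the 4644 calls in the same direction, and of the 932 others 5 had been called in the opposite direction. Of the 105 named genes that passed, 77 kept their call. The 27 that missed the threshold included NCOA2, CSF1, CCL20, HLA-B, TREM2, FCGR2A, ATG12, RB1CC1, FDPS, FASN, APOE, ACE, PLAUR, TBX21, BAK1, CASP8, BCL2L1, MCM2, BUB1, DNAJB9, ASNS, CALR, HERPUD1, CD5, GZMB and RPS6, while IRAK1 went from -0.57 to 0.01. Leaving out 1 library at a time ended the calls of NCOA2, TREM2, FCGR2A, ACAT2, IFNGR2, HERPUD1, FCGR1A, CD5, GZMB, RSAD2 and CXCL2 for at least 1 library each. With limma-voom in place of edgeR, NCOA2, CXCL3, CXCL2, CCL20, FCGR1A, VSIG4, BUB1, HERPUD1, MT1G and GZMB were not called; with surrogate variables BUB1 and VCAN were not, and with scaling by library totals APOE was not.

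**Figure D1:**
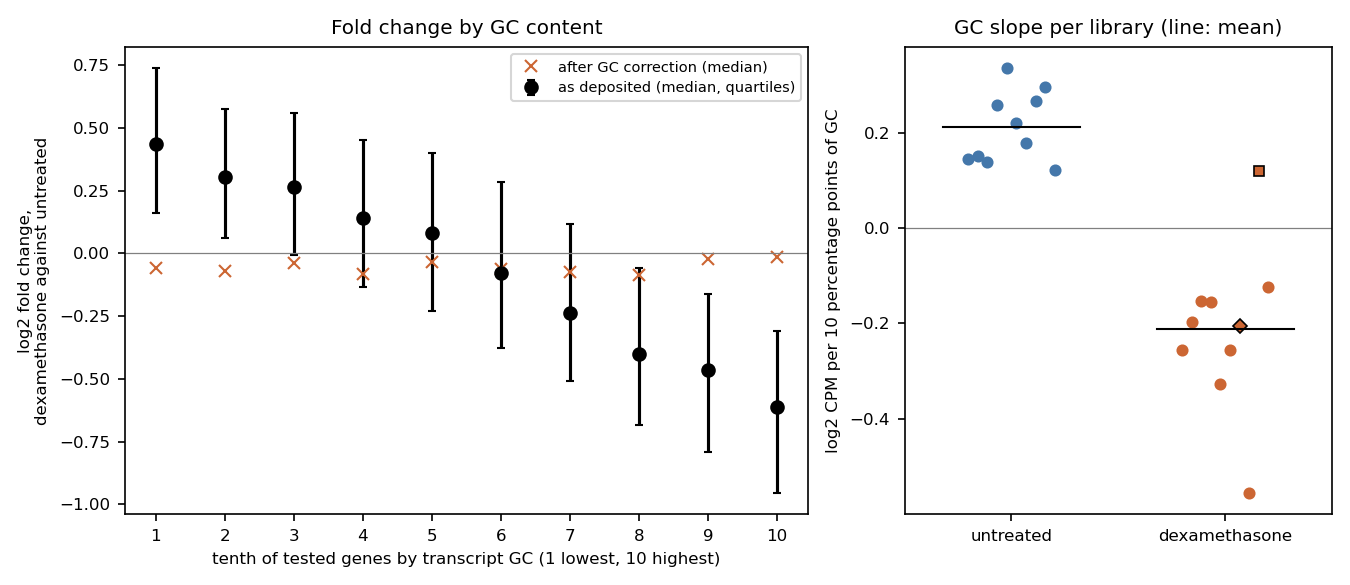
Log2 fold changes (dexamethasone against untreated) by decile of transcript GC content, and the slope of expression on GC in each library. The median log2 fold change falls from 0.44 in the tenth of genes with the least GC to -0.61 in the tenth with the most, and the slopes of the 10 dexamethasone libraries lie below those of the 10 untreated ones.

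The 23 pathway lists fixed before the data were examined gave 5 camera calls at an adjusted p of 0.05 with the preset correlation: glucocorticoid receptor targets, antigen presentation, lysosome, oxidative phosphorylation, and matrix remodelling. With an estimated correlation camera called 0 of the 23, with 2 at an unadjusted p under 0.05, and fry called 7. Among 100 splits of the 20 libraries into 10 and 10, 64 gave at least 5 camera calls, the real split included, so the number of camera calls did not separate the real groups from others. A permutation test of the list means, chosen after these results were seen, called 9 lists, including those 5. It asks whether a list differed between the groups and not whether it differed more than other genes.

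Most measured glucocorticoid receptor targets rose. Of 18 tested members 14 rose, 1 fell and 3 did not pass (15 and 1 adjusted over the list alone), with a median log2 fold change of 1.48. The camera adjusted p was 1.95e-05, and the list was lost at adjusted p = 0.174 with an estimated correlation. Without the library labelled dexamethasone replicate 7 that last value was 0.0122. The permutation adjusted p was 0.000287. DUSP1, a phosphatase that switches off MAP kinases, rose by 2.06 ± 0.27 on the log2 scale, GLUL, the glutamine synthetase, by 2.18 ± 0.32, and CD163, the haemoglobin scavenger receptor, by 3.19 ± 0.49 from 333 ± 210 to 3042 ± 1965 CPM. PDK4, a kinase that holds back pyruvate oxidation, rose 25.3-fold and PER1, a circadian clock gene, 3.79-fold. The kinase gene SGK1 went the other way, with a log2 fold change of -1.37 (edgeR adjusted p = 0.00177). ZBTB16 was too low in untreated cells to pass the count filter, with 17 counts over all untreated libraries and 60.7 ± 33.7 CPM in the dexamethasone group. In the fit without a filter its log2 fold change was 7.89 ± 0.75 (edgeR adjusted p = 6.98e-07). Of 10 tested genes of receptor handling 1 rose, 1 fell and 8 did not pass (0 and 1 adjusted over the list alone; camera adjusted p = 0.305, permutation adjusted p = 0.00143). Without dexamethasone replicates 7 and 9, 1 rose and 5 fell of 11. NCOA2, a co-activator, rose by 0.38 ± 0.14 with all libraries. HSD11B1, which regenerates active cortisol, had a log2 fold change of -1.03 ± 0.61, and FKBP4 of -0.36 ± 0.21. HSD11B1 stood at 179 CPM in the library labelled dexamethasone replicate 7 and at 7.89 ± 4.15 CPM in the other 9, against 57.6 ± 36.3 CPM untreated, and without that library it fell by 2.64 (edgeR adjusted p = 1.57e-05). Without dexamethasone replicate 9 FKBP4 fell by 0.53 (0.00917).

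In the library labelled dexamethasone replicate 7, these targets were not raised. It held 5216542 counts, with FKBP5 at 371 CPM against 1309 to 2079 in the other 9 dexamethasone libraries, TSC22D3 at 25.01 CPM, below all untreated libraries, and CD163 at 189 CPM. ZBTB16 had 0 counts there, which allows up to 0.651 CPM, while its lowest level elsewhere in the group was 37.8 CPM. Its mean log2 CPM over the receptor targets was 5.99, inside the untreated range of 5.31 to 6.11 and below the 7.26 to 8.09 of the other 9. ENG stood at 119 CPM and LGALS9 at 81.6 CPM there, below all untreated libraries. Both were among the genes with the smallest adjusted p in a comparison that included this library, so they do not test its label. IL8 reached 50396 CPM and IL1B 9635 CPM in this library. Without it, 4984 genes passed the edgeR threshold, 2384 higher and 2600 lower, and without replicates 7 and 9 together 5506 did.

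**Figure D2:**
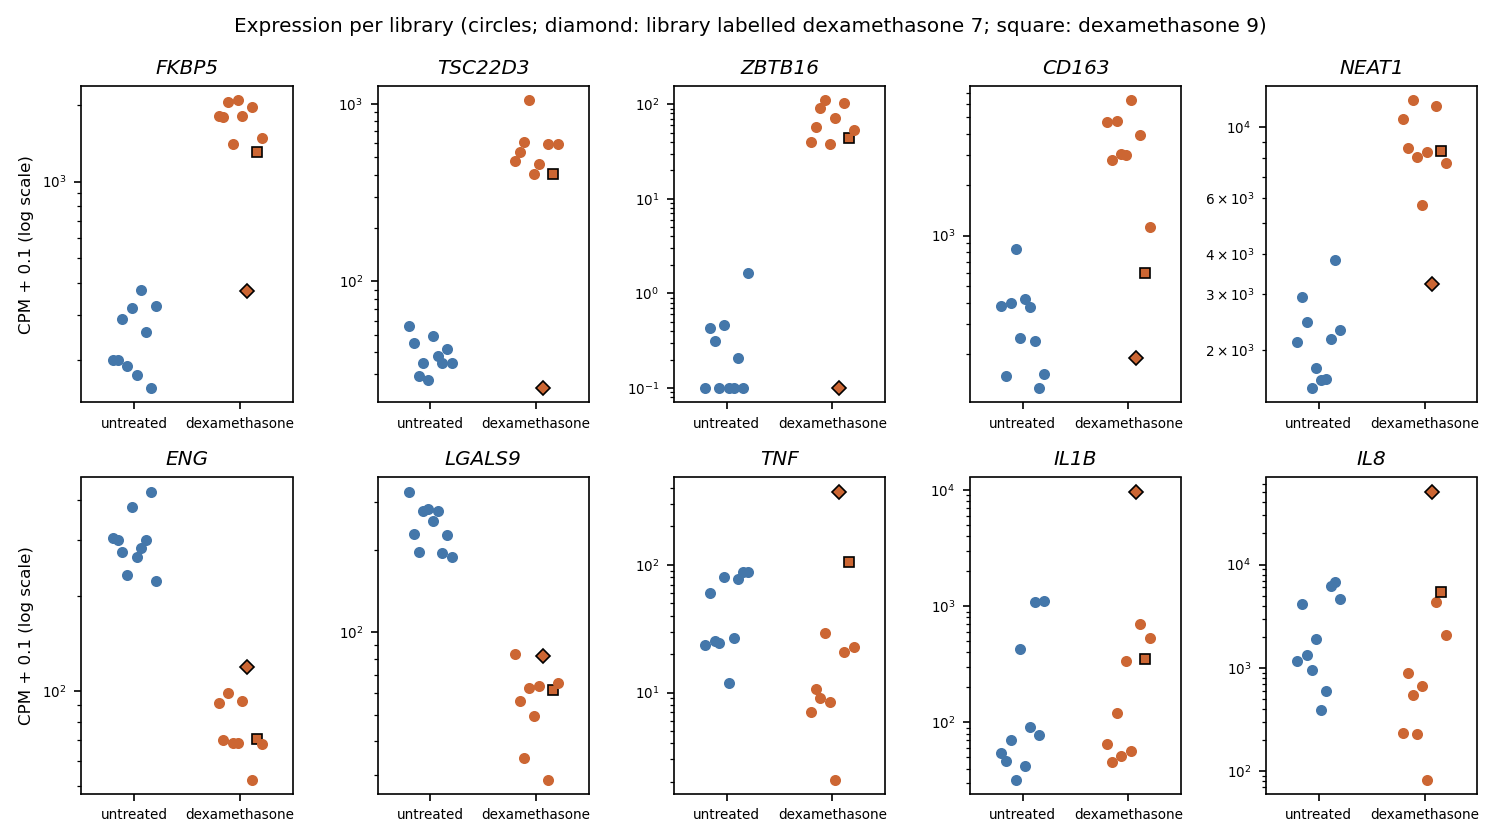
Expression of 10 genes in each library as CPM + 0.1 on a log scale, so that 0 counts sit at 0.1, for untreated and dexamethasone libraries. The diamond is the library labelled dexamethasone replicate 7, which lies among the untreated libraries for FKBP5, at 371 CPM, and above all others for IL8, at 50396 CPM, while its ENG level of 119 CPM lies below every untreated library; the square is replicate 9, which held 99634 counts.

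Transcripts of inflammatory cytokines depended on that 1 library. Of 9 tested members 1 fell and 8 did not pass (0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.302, direction down; permutation adjusted p = 0.181). Its median log2 fold change was 0.18 and its mean 0.26, opposite in sign to the test. TNF had a log2 fold change of 0.18 ± 0.72, IL1B of 1.98 ± 1.02, PTGS2 of 2.52 ± 1.24 and EREG of 1.41 ± 0.75, and none of the 4 passed. CSF1, a macrophage growth factor, fell by 2.25 ± 0.79 (edgeR adjusted p = 0.0253). IL6 did not pass the count filter, with 3.04 ± 5.45 and 86.2 ± 262 CPM, or 3.56 ± 6.25 CPM in the other 9 dexamethasone libraries. Without the library labelled dexamethasone replicate 7, 5 of the 9 fell, the median was -1.77 and the camera adjusted p 0.0283. With an estimated correlation the list was not called in that fit (camera adjusted p = 0.688), while the permutation adjusted p without that library was 0.0121. There TNF stood at -1.77 (edgeR adjusted p = 0.0105), PTGS2 at -2.04 (0.0428), CSF1 at -4.55 (4.1e-07) and IL1B at -0.29 (0.784). IL1RN, the secreted inhibitor of IL-1 chosen after its values were seen, stood at -5.42 (4.93e-07) without that library.

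Chemokines moved both ways. Of 19 tested members 4 rose, 4 fell and 11 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 0.02 and the mean 0.40, against a test pointing down (camera adjusted p = 0.290; permutation adjusted p = 0.452). In the fit that left out the library labelled dexamethasone replicate 7, 2 rose and 5 fell, with a median of -0.61, and after the GC correction 3 rose and 1 fell, with a median of -0.17. The neutrophil attractants CXCL3 and CXCL2 rose by 3.44 ± 0.83 and 2.76 ± 0.82, and CCL20, which draws CCR6-bearing lymphocytes, by 2.5 ± 0.76. CXCL16 fell by 0.86 ± 0.18. IL8 (1.21 ± 0.93, edgeR adjusted p = 0.305) and CCL18 (-0.66 ± 0.42, 0.213) did not pass. Without the library labelled dexamethasone replicate 7 the log2 fold change of CXCL3 was 1.84 (edgeR adjusted p = 0.0143) and that of CXCL2 1.18 (0.142), while IL8 stood at -0.82 (0.356). CCL24 and CCL22, chosen after their values were seen, stood at -8.64 and -4.39 there, against -2.91 and -2.10 with all libraries.

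Innate sensing genes also moved both ways. Of 23 tested Toll-like receptor and NF-kB genes 7 rose, 3 fell and 13 did not pass, in the same numbers adjusted over the list alone (camera adjusted p = 0.630, permutation adjusted p = 0.452). TLR2, which senses bacterial lipoproteins, rose from 88.8 ± 68.7 to 808 ± 527 CPM (log2 fold change 3.18 ± 0.49), and IRAK3, an inhibitor of the pathway, by 1.85 ± 0.19. The adaptor MYD88 fell by 1.06 ± 0.15, and the kinase gene IRAK1 by 0.57 ± 0.10. Of 23 interferon response genes 1 fell and 22 did not pass (0 adjusted over the list alone; camera adjusted p = 0.630, permutation adjusted p = 0.756). These tests left out the replicate number and do not show that the interferon response genes were unchanged. RSAD2, which encodes the antiviral enzyme viperin, fell by 2.04 ± 0.71, while IFIT3, OAS1 and IFIT2 had log2 fold changes of 0.85 ± 0.46, 0.42 ± 0.25 and 0.61 ± 0.37. OAS1 rose by 0.54 without the library labelled dexamethasone replicate 7 (edgeR adjusted p = 0.0459).

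Antigen presentation genes fell or did not pass. Of 22 tested members 12 fell and 10 did not pass (13 fell adjusted over the list alone), with a median log2 fold change of -0.61. The camera adjusted p was 0.00258 and the permutation adjusted p 0.0122, with adjusted p = 0.821 with an estimated correlation. The costimulatory receptor gene CD86 fell from 197 ± 82.8 to 66.5 ± 28.8 CPM (log2 fold change -1.54 ± 0.25), HLA-B by 0.80 ± 0.16, the immunoproteasome subunit PSMB8 by 1.06 ± 0.23 and HLA-DMA, which loads class II molecules, by 0.80 ± 0.19. After the GC correction 8 members fell, and with that correction and without dexamethasone replicates 7 and 9 the list was not called (camera adjusted p = 0.0749). Of 15 tested genes of T-helper polarising signals and the JAK-STAT pathway, 3 rose, 1 fell and 11 did not pass, in the same numbers adjusted over the list alone. The median was 0.04 (-0.10 without the library labelled dexamethasone replicate 7), the mean -0.06 and the test pointed up (camera adjusted p = 0.630, permutation adjusted p = 0.719). IFNGR1 rose by 1.5 ± 0.23, JAK1 by 0.59 ± 0.14 and IFNGR2 by 0.59 ± 0.22, and TBX21, a transcription factor of T-helper and NK cells, fell by 2.22 ± 0.68, beside a median of -1.06 for the T cell markers.

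Lysosomal genes fell or did not pass. Of 20 tested members 13 fell and 7 did not pass (15 fell adjusted over the list alone), with a median log2 fold change of -0.78. The camera adjusted p was 0.000103 and the permutation adjusted p 0.000287, with adjusted p = 0.434 with an estimated correlation. The glycosidase gene GLA fell by 1.48 ± 0.21, TFEB, the transcription factor of lysosome formation, by 1.90 ± 0.29, and the calcium channel gene MCOLN1 by 1.12 ± 0.18. After the GC correction 11 fell. Of 15 autophagy genes 5 rose, 2 fell and 8 did not pass (5 and 4 adjusted over the list alone). The median was -0.02, the mean 0.11 and the test pointed up (camera adjusted p = 0.630, permutation adjusted p = 0.258). After the GC correction 2 rose and 4 fell. ATG12 rose by 0.71 ± 0.12, RB1CC1 by 0.81 ± 0.18 and WIPI1 by 1.17 ± 0.28, and TFE3, a relative of TFEB, fell by 0.77 ± 0.13.

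Genes of mitochondrial respiration mostly fell. Of 21 tested oxidative phosphorylation genes 14 fell and 7 did not pass (1 rose and 15 fell adjusted over the list alone), with a median log2 fold change of -0.46. The camera adjusted p was 3.52e-05 and the permutation adjusted p 0.000287, with adjusted p = 0.434 with an estimated correlation. CYC1, ATP5B, UQCRC1 and NDUFB8, which belong to complexes of the respiratory chain and to ATP synthase, fell by 1.17 ± 0.16, 0.91 ± 0.13, 0.94 ± 0.14 and 0.86 ± 0.13. After the GC correction 15 fell. Of 16 genes of glycolysis and the hypoxia response 2 rose, 7 fell and 7 did not pass, in the same numbers adjusted over the list alone (camera adjusted p = 0.302, permutation adjusted p = 0.480). The glycolytic enzyme genes PKM, ALDOA, ENO1 and PFKP fell by 1.10 ± 0.15, 0.88 ± 0.14, 0.83 ± 0.15 and 0.94 ± 0.19.

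Matrix and granuloma genes fell or did not pass. Of 17 tested members 8 fell and 9 did not pass, in the same numbers adjusted over the list alone, with a median log2 fold change of -1.06. The camera adjusted p was 0.000311 and the permutation adjusted p 0.000287, with adjusted p = 0.174 with an estimated correlation, which was 0.0122 without the library labelled dexamethasone replicate 7. MMP9 fell by 4.06 ± 0.59, the urokinase gene PLAU by 1.77 ± 0.35, its receptor gene PLAUR by 1.06 ± 0.32 and ACE, the angiotensin-converting enzyme used as a marker of sarcoidosis, by 0.93 ± 0.23. Without that library 12 fell, and after the GC correction 5 did. TIMP3, which missed the count filter and was chosen after its values were seen, stood at 39.6 ± 46.3 and 0.833 ± 1.37 CPM. In the library labelled dexamethasone replicate 7 it stood at 4.57 CPM, and in the other 9 dexamethasone libraries at 0.418 ± 0.415 CPM.

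**Figure D3:**
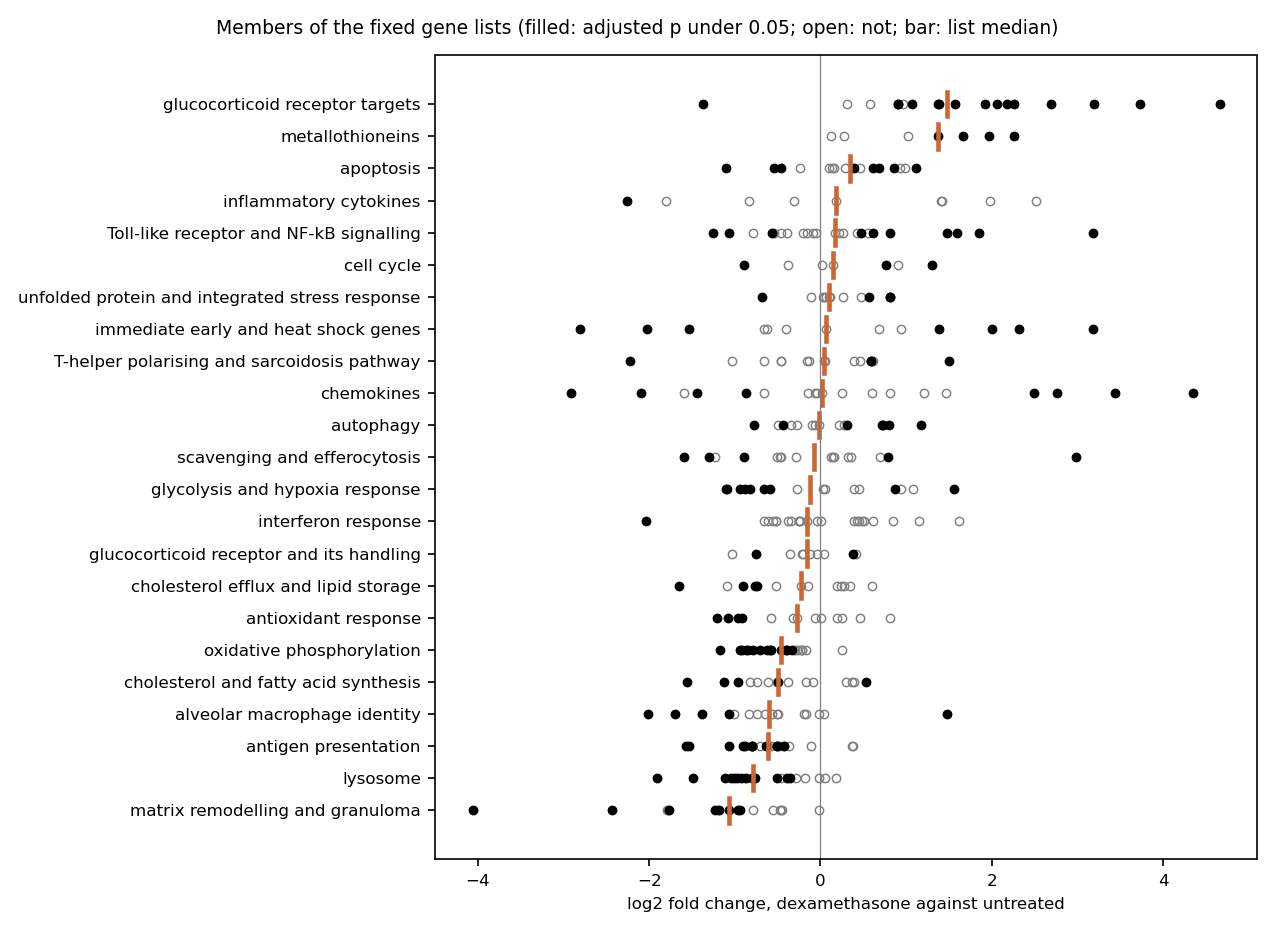
Log2 fold changes of the tested members of the 23 pathway lists, with filled circles for genes at an adjusted p under 0.05 in edgeR's quasi-likelihood test, open circles for others and a bar at each list's median. The median lies at 1.48 for the glucocorticoid receptor targets and at -1.06 for the matrix genes.

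Scavenger and identity genes of macrophages split. Of 16 tested scavenging and efferocytosis genes 2 rose, 3 fell and 11 did not pass, in the same numbers adjusted over the list alone. Median and mean were -0.08 and -0.07 (median 0.24 without the library labelled dexamethasone replicate 7) while the test pointed up (camera adjusted p = 0.801, permutation adjusted p = 0.480). CD163L1, a relative of CD163, rose by 2.98 ± 0.39 and the Fc receptor gene FCGR2A by 0.79 ± 0.29. The lipid receptor gene TREM2 fell by 1.6 ± 0.56 and the Fc receptor gene FCGR1A by 1.31 ± 0.46. Without the library labelled dexamethasone replicate 7 the edgeR adjusted p of FCGR2A was 0.0556. MERTK, a receptor for uptake of dying cells that missed the filter and was chosen after its values were seen, stood at 1.91 ± 1.82 and 23.9 ± 24.6 CPM. Of 16 alveolar macrophage identity genes 1 rose, 4 fell and 11 did not pass (1 and 3 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.207, permutation adjusted p = 0.0176). FBP1, a gluconeogenic enzyme gene, fell by 1.70 ± 0.31, the transferrin receptor gene TFRC by 1.38 ± 0.34 and APOC1 by 1.06 ± 0.27, while VSIG4, a complement receptor gene, rose by 1.48 ± 0.39.

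Regulators of lipid metabolism were among the fallen genes. Of 15 tested genes of cholesterol and fatty acid synthesis 1 rose, 4 fell and 10 did not pass (0 and 4 adjusted over the list alone; camera adjusted p = 0.290, permutation adjusted p = 0.0246). The library labelled dexamethasone replicate 7 was highest for this list among the dexamethasone libraries, and without it 0 rose and 7 fell, while after the GC correction 0 rose and 2 fell. The master regulators SREBF1 and SREBF2 fell by 1.55 ± 0.27 and 1.13 ± 0.25, and the synthetic enzyme genes FDPS and FASN by 0.49 ± 0.14 and 0.96 ± 0.32. Of 13 tested members of the list fixed as cholesterol efflux and lipid storage 4 fell and 9 did not pass, in the same numbers adjusted over the list alone (camera adjusted p = 0.603, permutation adjusted p = 0.0313). NR1H3, the oxysterol receptor LXR-alpha, fell by 1.65 ± 0.32, NCEH1 by 0.77 ± 0.24 and APOE by 0.74 ± 0.26. ACAT2, counted here only because the list held its symbol, fell by 0.90 ± 0.31.

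The remaining pathway lists were not called by camera. Of 7 tested metallothioneins, small metal-binding proteins, 4 rose and 3 did not pass, in the same numbers adjusted over the list alone, with a median of 1.37 (camera adjusted p = 0.194, permutation adjusted p = 0.0755). These were MT1X (2.26 ± 0.43), MT1E (1.97 ± 0.52), MT1G (1.67 ± 0.57) and MT2A (1.37 ± 0.43). After the GC correction this list was called at the preset correlation (camera adjusted p = 0.0152). Its estimated correlation was 0.873, and with that value and no GC correction the camera adjusted p was 0.821. Of 13 antioxidant genes 4 fell and 9 did not pass, in the same numbers adjusted over the list alone (camera adjusted p = 0.290, permutation adjusted p = 0.169), and TXNRD1, SRXN1, PRDX1 and NQO1 fell by 1.20 ± 0.36, 1.08 ± 0.21, 0.96 ± 0.17 and 0.92 ± 0.22. Of 16 apoptosis genes 5 rose, 3 fell and 8 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.352, permutation adjusted p = 0.452), and after the GC correction 2 rose and 0 fell. CFLAR and CASP8 rose by 0.86 ± 0.20 and 0.69 ± 0.18, and BAK1 and BCL2L1 fell by 1.10 ± 0.25 and 0.54 ± 0.15.

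Of 13 immediate early and heat shock genes 4 rose, 3 fell and 6 did not pass (4 and 5 adjusted over the list alone). The median was 0.06 and the mean 0.20 while the test pointed down (camera adjusted p = 0.290, permutation adjusted p = 0.480). Without dexamethasone replicates 7 and 9, the latter highest for this list and for FOS, 1 rose and 6 fell of 14, with a median of -0.43. EGR2 fell by 2.81 ± 0.55, HSPB1 by 1.53 ± 0.33 and ATF3 by 2.03 ± 0.58, and FOS rose by 1.38 ± 0.41. Of 12 genes of the unfolded protein response 3 rose, 1 fell and 8 did not pass, in the same numbers adjusted over the list alone (camera adjusted p = 0.623, permutation adjusted p = 0.234), and after the GC correction these 4 calls ended. DNAJB9, ASNS and HERPUD1 rose by 0.81 ± 0.20, 0.81 ± 0.25 and 0.57 ± 0.22, and CALR fell by 0.68 ± 0.21. Of 7 tested cell cycle genes 2 rose, 1 fell and 4 did not pass, in the same numbers adjusted over the list alone (camera adjusted p = 0.705, permutation adjusted p = 0.671), and after the GC correction 1 rose and 0 fell. PCNA and BUB1 rose by 0.76 ± 0.15 and 1.30 ± 0.37, MCM2 fell by 0.89 ± 0.22, and TOP2A had a log2 fold change of 0.91 ± 0.48. Without the library labelled dexamethasone replicate 7 TOP2A rose by 1.08 (edgeR adjusted p = 0.0387), and without untreated replicate 10 by 1.21 (0.0422).

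Markers of T and NK cells, which a lavage preparation can hold, varied widely between libraries. The mean log2 CPM of the T cell markers was 3.55 ± 1.90 in untreated and 2.64 ± 1.82 in dexamethasone libraries (permutation p = 0.285, adjusted p = 0.372), and that of the NK cell markers 1.56 ± 1.39 and 0.25 ± 1.03 (0.0276, 0.0671). These tests left out the replicate number and do not show that the content of T and NK cells was alike in the groups. Of 10 tested T cell genes CD5 fell by 1.28 ± 0.47 and 9 did not pass (0 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 0.131, permutation adjusted p = 0.274), and CD3D had a log2 fold change of -1.92 ± 0.81. CD3D passed as a fall without any 1 of untreated replicates 1, 2, 6 and 9 and dexamethasone replicate 10 (fits from -2.06 to -2.47). Of the 2 testable NK cell genes GZMB fell by 2.82 ± 1.0 (1 adjusted over the list alone) and PRF1 did not pass (-1.17 ± 0.82). Of 5 tested monocyte genes 3 rose and 2 did not pass, in the same numbers adjusted over the list alone, with camera adjusted p = 0.0562 and permutation adjusted p = 0.0187. S100A8 rose by 1.58 ± 0.26 and VCAN by 1.94 ± 0.45. Macrophages express several of these monocyte genes too. Neutrophil (CSF3R, -0.55 ± 0.29), dendritic (LAMP3, -0.16 ± 0.59, and CCR7, 0.07 ± 0.77) and erythroid (HBB, 0.29 ± 0.73) markers did not pass, in counts of 1, 2 and 1 tested genes (0 adjusted over each list alone). None of the B cell, mast cell or epithelial markers passed the count filter, and their mean log2 CPM was at most -0.37 in either group.

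RNA composition differed between the groups. Nuclear-retained RNAs were higher with dexamethasone: of 4 tested, 3 rose and 1 did not pass, in the same numbers adjusted over the list alone, with a median of 1.07. The camera adjusted p was 0.0248 and the permutation adjusted p 4e-04, with adjusted p = 0.270 with an estimated correlation. NEAT1, the scaffold of paraspeckles, rose from 2239 ± 715 to 8447 ± 2657 CPM (log2 fold change 1.92 ± 0.22) and KCNQ1OT1 by 1.34 ± 0.38. In the library labelled dexamethasone replicate 7 NEAT1 stood at 3236 CPM, inside the untreated range of 1525 to 3837 CPM. The other dexamethasone libraries held 5692 to 12125 CPM. The MALAT1 share of that library was 4.01%, above the highest untreated share of 3.84%. MALAT1 took 2.61 ± 0.790% of counts in untreated and 4.66 ± 1.57% in dexamethasone libraries (permutation p = 0.00019, adjusted p = 0.00108 over 17 measures), and the 50 most abundant genes 17.7 ± 0.906 and 19.5 ± 1.78% (p = 0.00443, adjusted p = 0.0151, permutation test). Of 14 ribosomal protein genes 3 rose and 11 did not pass (2 adjusted over the list alone; camera adjusted p = 0.0562, permutation adjusted p = 0.0187), with RPL23 at 0.71 ± 0.15 and RPS6 at 0.48 ± 0.16. Untreated replicate 3 was low for this list, and without it the difference in mean log2 CPM went from 0.44 to 0.25 (permutation adjusted p = 0.0277). Transcripts encoded by the mitochondrial genome were not analysed here. Without dexamethasone replicates 7 and 9 the nuclear-retained list had a camera adjusted p of 0.0511. After the GC correction 2 of its 4 tested members rose, with a median of 0.70, and camera still called it.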

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

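The tests of depth, of preparation or sequencing, of the GC trend as the whole cause, of a swap, of too few reads and of unexposed cells were chosen only after the result was seen, while those of NR3C1, neutrophils, matched gene lists and other splits were set beforehand. Of 332 groups of values screened for 1 library far from the rest, 44 held one, where chance gives about 1 in 20, or 16.6. Of these 44, 15 genes and 3 lists belonged to the library labelled dexamethasone replicate 7, and 11 genes, 2 library measures and 1 list to dexamethasone replicate 9.

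Transcripts rich in GC were lower and those poor in GC higher with dexamethasone. Lower depth was argued against, since among the 6 dexamethasone and 10 untreated libraries with at least 2117044 counts the slopes still differed by -0.444 (permutation p = 0.00015). The trend was not the whole cause of the changed genes: 45.5% kept their call and direction after the correction, while the 2533 others, 5 of them called in the opposite direction, went from a median absolute log2 fold change of 0.60 to 0.22, with median SE of 0.168 and 0.159, so the typical call ended because the change shrank. The library labelled dexamethasone replicate 7 had untreated levels of the receptor targets and a slope of -0.205, outside the untreated range of 0.122 to 0.335, so a difference in library preparation or sequencing between the groups, without dexamethasone, is a candidate explanation that rests on 1 library. The labels give no batch, any batch that followed the groups would be confounded with them, and an effect of dexamethasone itself on GC-rich transcripts stays open.

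The library labelled dexamethasone replicate 7 lacked the rise of the receptor targets. A swap with an untreated library and too few reads were both excluded: the highest untreated score was 6.11, against 7.26 for the lowest of the other dexamethasone libraries, and 174 ZBTB16 reads would be expected there where 0 were counted. Neutrophils did not bring its IL8 and IL1B, since the mean over 9 neutrophil markers was -0.584, below the highest of the other 19 libraries at 0.343. NR3C1 stood at 505 CPM, above the 245 to 453 CPM of the other 19, which argues against a low receptor transcript; the bound set beforehand foresaw a value inside that range, and a value above it was read this way only after it was seen. Its score of 5.99 lies inside the untreated range, so cells not exposed to dexamethasone may be the source. The library was not like the untreated ones in all respects. Its mean log2 CPM of inflammatory cytokines was 10.4, against 8.70 in the highest untreated library, and its IL1B 9635 CPM, against 1100 CPM. However, a wrong label, a failed addition and cells that did not respond were not told apart. Its GC slope followed the label. So did its ENG and LGALS9, but these were top genes of a comparison that included this library, so they do not test the label.

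Genes of oxidative phosphorylation, the lysosome and matrix remodelling were lower than random genes of like GC content. Among 10000 random lists matched on GC, the medians of -0.46, -0.78 and -1.06 lay at percentiles 0.06, 0.01 and 0.01, the last 2 being the smallest that 10000 lists can give, against random medians of -0.01, -0.11 and -0.23. Short transcripts did not account for the first list either, at percentile 0.73 among lists matched on length, with a random median of -0.03. Random lists do not keep the correlation between members of a pathway, and with an estimated correlation the 3 lists were not called (adjusted p = 0.434, 0.434 and 0.174). A response to dexamethasone may account for the lower lists, as a hypothesis, while a preparation difference that does not act through GC or length was not tested.

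The real grouping gave 4644 changed genes, as many as in 1 of 100 splits of the 20 libraries, the real one itself. That is the smallest share 100 splits can give, so chance is an unlikely source of this number. The splits treat all 20 libraries as exchangeable and cannot tell dexamethasone from a batch that followed the groups. The highest of the other splits gave 1831 and kept 9 of the 10 untreated libraries together. For the number of camera calls chance was not excluded, since 64 of 100 splits gave at least the 5 of the real one, and the highest other gave 13.

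The library labelled dexamethasone replicate 7 stood far from the other dexamethasone libraries in the mean log2 CPM of receptor targets (5.994, next 7.261), inflammatory cytokines (10.4, next 7.124) and cholesterol synthesis (6.269, next 5.5). It was lowest for FKBP5 (370.8 CPM), FMN1 (62.86), TSC22D3 (25.01), SESN1 (25.66), DUSP1 (154.2), GLUL (489.1), NCOA2 (33.28), VSIG4 (21.53) and TOP2A (0.6525), and highest for CSF1 (2488), PTGS2 (5272), IL1B (9635), PLAU (90.91), PLAUR (955.7) and IL6 (830.4).

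Dexamethasone replicate 9 stood apart with 9203 genes counted (next 13170), a score of 254.7 on the first component, and 9.209 for immediate early and heat shock genes. With 99634 counts in that library, POLD1, FAM89B, SREBF1, ACAT2, BAK1 and VCAN had 0 CPM, which allows up to 26.3 CPM at 3 counts, above the next value of each (4.514, 15.85, 14.63, 7.944, 13 and 14.64), so these zeros do not set it apart; PSMB8 and NR1H3 8.787 and ATG12 35.15, while FASN (123) and FOS (579.9) were highest. Dexamethasone replicate 8 was highest in the share of MALAT1 (8.489%, next 5.721) and lowest for NDUFB8 (18.06 CPM), and dexamethasone replicate 4 was lowest for monocyte genes (mean log2 CPM 1.563). Among untreated libraries, replicate 3 was lowest for ribosomal protein genes (mean log2 CPM 5.612), replicate 6 lowest for HLA-B (2095 CPM), replicate 9 highest for CXCL2 (116.4) and NQO1 (117.1), and replicate 1 highest for ACAT2 (66.86). Untreated replicate 10 was lowest for MCOLN1 (43.65), CYC1 (48.28) and UQCRC1 (106.9), and highest for CASP8 (79.37).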

How the results depend on the processing

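The GC corrections, the permutation of list means and the fits with libraries left out were tests chosen only after the result was seen. Planned settings other than a minimum fold gave 4534 to 5954 changed genes, and leaving out 1 library at a time gave 4154 (without dexamethasone replicate 8) to 5210 (without dexamethasone replicate 9), 1997 to 2549 higher and 2157 to 2661 lower. With a minimum absolute log2 fold change of 1 there were 1200 (517 higher and 683 lower), by construction fewer. The GC correction gave 3043 (1291 higher), and with the replicate block 4264. The block alone gave 5527 (2574 higher and 2953 lower) and 7 called pathway lists, with alveolar macrophage identity (adjusted p = 0.00536) and metallothioneins (0.00737) added. Under it 6 interferon genes rose and 7 fell, 1 of 10 T cell genes rose and 6 fell, and 2 of 2 tested NK cell genes fell. With the block 17 antigen presentation genes fell, and FKBP4, HSD11B1, IFIT3, OAS1, CD3D, PRF1 and CCL18 passed. NR3C1 passed as a fall with the GC correction and the block, and with the GC correction without dexamethasone replicates 7 and 9. Over 35 alternatives its log2 fold change ran from -0.418 to -0.001. As a hint from the data and not the design, 9 of 10 same-numbered pairs correlated above 0.1 (0.0126 to 0.698 over all 10). The pair below 0.1 was number 7, whose dexamethasone library lacked the rise of the receptor targets. Computed without dexamethasone replicates 7 and 9, the other pairs correlated at 0.349 to 0.712. Among all libraries, 7 untreated and 8 dexamethasone ones correlated best with their own number. This did not meet the rule for pairing set beforehand. The model with the group only therefore stayed the main one, and it can miss changes that follow the replicate number. Of the 105 called named genes, limma-voom kept 95, with quality weights 100 (CXCL3, CXCL2, CCL20, MT1G and GZMB lost in both), the fit without the library labelled dexamethasone replicate 7 kept 103, and the GC correction 77.

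Of 23 pathway lists, an estimated correlation called 0 (2 at an unadjusted p under 0.05), fry 7, and permutation of list means 9, 10 without the library labelled dexamethasone replicate 7 and 9 without untreated replicate 3. Leaving out 1 library at a time gave 5 to 6. Over 34 alternatives the adjusted p ran from 1.69e-11 to 0.174 for receptor targets, 2.57e-07 to 0.434 for oxidative phosphorylation, 9.17e-07 to 0.434 for the lysosome, 2e-06 to 0.174 for matrix genes and 1.78e-05 to 0.821 for antigen presentation. Of the 4 lists of other cells and RNA quality, 1 was called. An estimated correlation called 0 (0 at an unadjusted p under 0.05), the fit without dexamethasone replicates 7 and 9 called 0 (1 at an unadjusted p under 0.05), fry, DESeq2 size factors, quality weights and the replicate block 2 each, and the GC correction (alone, with the block, or without replicates 7 and 9) and permutation of list means (with all libraries, without replicate 7 or without untreated replicate 3) 3 each. Leaving out 1 library at a time gave 1 to 3.

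TNF reversed to -1.89 with quality weights, -1.77 without dexamethasone replicate 7, -2.02 without replicates 7 and 9, and -1.80 with a GC correction besides. PTGS2 reversed to -2.04, -2.26 and -2.81 in the last 3 of these. Where replicate 7 was left out, its high level of both genes is the cause, and with quality weights the cause was not tested. Leaving out any other single library gave up to 0.35 for TNF and 3.17 for PTGS2. IRAK1 reversed to 0.0149 with the GC correction, 0.0156 with the block besides and 0.0157 without replicates 7 and 9, and IL8 to -1.68 with GC correction and block; the cause was not tested. IL8 stood at -1.99 with GC correction without replicates 7 and 9, -1.31 without both and no correction, and -0.82 without replicate 7 alone, and IL1B at -0.29 without replicate 7, so leaving out that library turned their sign. Depth limits low genes most in dexamethasone replicate 9, where 1 read is worth more CPM than in any other library.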

Other observations

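The genes in this part were chosen after their values were seen, and their log2 fold changes with SE come from edgeR's quasi-likelihood test. THBS1, the matrix protein thrombospondin-1, rose by 5.31 ± 0.85 (adjusted p = 7.6e-05), from 16.6 ± 11.03 to 657 ± 849 CPM, and MFGE8, a bridge between dying cells and phagocytes, by 3.29 ± 0.41 (8.2e-06), from 5.86 ± 3.66 to 58.8 ± 23.6 CPM. The formyl peptide receptor genes FPR1 and FPR2 rose by 3.48 ± 0.58 and 2.72 ± 0.63, while FPR3 fell by 1.24 ± 0.40. ALOX15B, a lipoxygenase gene, rose by 4.14 ± 0.81, TFPI, an inhibitor of coagulation, by 2.51 ± 0.37, and the chemokine receptor gene CXCR4 by 2.05 ± 0.39. ANXA1, a glucocorticoid-regulated protein that signals through formyl peptide receptors, did not pass (-0.26 ± 0.24, adjusted p = 0.403).

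The clock gene PER1 rose by 1.92 ± 0.31, PER2 fell by 1.53 ± 0.29 and PER3 by 1.01 ± 0.31, the repressor gene BHLHE40 fell by 1.34 ± 0.32 and NFIL3 rose by 1.57 ± 0.22. ARNTL did not pass (0.19 ± 0.13, adjusted p = 0.244). TXNIP and ARRDC3, of the arrestin domain family, rose by 1.43 ± 0.19 and 2.49 ± 0.28, and PIK3IP1, an inhibitor of PI3 kinase, by 2.41 ± 0.41. COL8A2 fell by 2.89 ± 0.37, COL6A1 by 2.40 ± 0.47 and SPARC by 1.86 ± 0.21. CRABP2, which carries retinoic acid, fell by 5.35 ± 0.68, from 16.3 ± 13.0 to 0.313 ± 0.649 CPM, and IFI30, a lysosomal thiol reductase gene, by 1.18 ± 0.13.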
